A study of Mus musculus with 6 samples.

How the data were processed

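RNA was measured by sequencing in whole hearts of mice at postnatal day 1. The 6 libraries fall into 2 groups of 3. FF hearts came from mice labelled Flox with the genotype FF, and cKO hearts from mice with a cardiac knockout of Kdm5b, per the labels. Kdm5b encodes a demethylase of lysine 4 of histone H3. FF mice are taken here as controls with floxed alleles of that gene, which their labels do not state. The labels number the samples within each group and do not say whether each came from a separate animal, so the p-values measure the spread between these samples. Total RNA was extracted with the miRNeasy micro kit and libraries were made with the Ovation Ultralow V2 kit, per the labels' protocols.

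The authors deposited FPKM values, that is fragments per kilobase of gene length scaled to a library size, for 56748 genes in 6 columns, per the file headers. The submitters' processing notes name FastQC, TopHat2 2.0.13, Subread, featureCounts and edgeR with no order, and the builds GRCh38, mm10 and GRCm39 with no role. The annotation release and the strand setting of the counting are not given in the sources used here, so genes that overlap on either strand may share reads. Of 52073 gene identifiers shared with GENCODE M21, which is on GRCm38 (mm10), only 1472 had the same start and end in both. Coordinates are printed as the deposited table gives them, and of the mouse builds named in the notes this leaves GRCm39.

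FPKM multiplied by gene length was a whole multiple of a single step per library. Values under 200 reads were checked, and 100% of them lay within 0.1 of a whole number in each library, which gave back the reads behind each value. The libraries held between 15658893 and 20339926 such reads. The library size behind the deposited FPKM was 0.960 to 1.07 times that total, so a scaling factor per library had been applied, and its method is not given in the sources used here. The precision of a gene follows from its reads, and 95% exact Poisson intervals are given for Kdm5b, which cover counting error only.

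Differences were tested with limma 3.58.1 in R 4.3.3 on log2(FPKM + 1), with group as the only term, an intensity trend in the variance prior and Benjamini-Hochberg adjustment at 0.05. The 12678 genes with a mean FPKM of at least 1 over the 6 libraries were tested. Log2 differences are cKO minus FF on the log2(FPKM + 1) scale, which understates the change of low genes. Values of groups are means ± SD with n = 3. For Kdm5b a two-sided exact permutation test was added, whose smallest p with 3 against 3 is 0.1. The test, the filter, the named genes, the gene lists and most alternatives were set before the data were examined.

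A total of 48 gene lists covered the cell cycle, chromatin regulators, heart muscle, metabolism, stress responses and markers of other cell types and neighbouring tissues. The 42 lists with at least 5 tested members were tested with limma camera at a preset correlation of 0.01 and Benjamini-Hochberg adjustment over the lists. Camera with an estimated correlation and fry were run beside it. For each list the members past the threshold were counted after adjustment over all genes tested and after adjustment over the list alone. The other 6 lists (germline, granulocyte, platelet, lung, skeletal muscle and liver markers) had 1 to 4 tested members and gave no list test.

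The genes named below were chosen by a fixed rule. It took Kdm5b and its 3 paralogues, up to 12 genes per direction with the largest log2 difference among those past the threshold whose group values did not overlap, up to 4 called members of each list or, with none, the 2 members with the smallest p as values, and 17 fixed heart, cell cycle and sex-linked genes. Predicted genes, names ending in Rik, pseudogenes and genes of the mitochondrial genome were left out of the part on the largest differences. The text names 18 of the 19 genes past the threshold that the rule picked. Trbc1, Tcf7, Lck, Cd8b1, Myl7 and Sln were added after their values were seen.

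The steps were tested on simulated libraries with the real gene means and library sizes and 200 changed genes. With 6 alike libraries for cKO against FF, limma recovered 100% of the genes changed by 4-fold and 99.0% of those changed by 2-fold among 12680 genes tested, with 14 false calls. With the spread of the third FF library added, it recovered 90.0% and 48.0% among 12759 genes tested, with 2 false calls. A simulated list of 40 genes shifted by -0.50 was called by camera in both cases, and 0 of the 42 real lists were. Genes of the simulation varied independently of each other, so it could not test camera where members of a list move together.

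Alternatives were other pseudocounts (0.1 and 0.5), no filter or a mean FPKM of at least 5, median-ratio scaling, quantile normalization, rescaling outside the mitochondrial genome and haemoglobin genes, robust variance priors, library weights, protein-coding genes alone, the replicate number as a block, and leaving out each library. Chosen after seeing the data were a GC correction (a natural spline with 5 degrees of freedom per library, with GC content from GENCODE M21 transcripts for 98.4% of the tested genes), limma voom on the recovered reads with and without quality weights, a term for the libraries with Y-linked reads, and combinations without the third FF library. Read counts of libraries of the same group differed by 10.1 to 134 times the sampling noise (chi-square per degree of freedom), so no library was counted as a duplicate.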

Results

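The hearts of newborn mice were profiled to ask which genes depend on Kdm5b, in a study that searched for chromatin regulators of cell cycle genes in heart muscle cells. Gene expression was given as FPKM in 3 FF control hearts and 3 cKO hearts at postnatal day 1, with 15658893 to 20339926 reads per library. FF replicate 3 stood apart from the other 5 libraries. Its correlation with them across genes was 0.880 to 0.909, against 0.954 to 0.984 among the others, and the first principal component, with 58.4% of the variance, set it apart. Transcripts of thymocytes were abundant in it, with Trbc2 at 109 FPKM against at most 1.02 in the other libraries. Its deviations from the mean of the 6 libraries rose with the GC content of the gene (Spearman's rho 0.618 across genes, which are not independent replicates). The other libraries had -0.48 to -0.05, which in part mirrors FF replicate 3, since that mean includes it. Counts that depend on FF replicate 3 are therefore given with and without it.

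**Figure D1:**
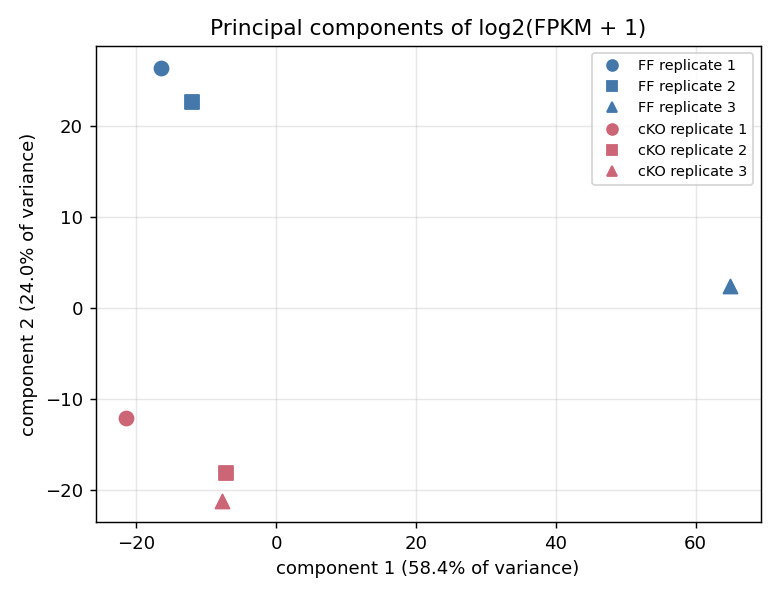
Principal components of log2(FPKM + 1) over the 12678 tested genes, with each library as a point (blue FF, red cKO, marker shape by replicate number) and each axis giving a component's score and its share of variance. FF replicate 3 lies alone at 65.0 on the first component, and the other 5 libraries lie between -21.5 and -7.17.

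Kdm5b itself (ENSMUSG00000042207, chromosome 1, 134487909 to 134563023, plus strand) was read in all 6 libraries and differed little between the groups. Its level was 3.45 ± 0.406 FPKM in FF and 2.86 ± 0.149 FPKM in cKO hearts (SD, n = 3 each), 17.3% lower in cKO. The 3 cKO values, 2.80, 3.03 and 2.75 FPKM, all lay below the FF values of 3.19, 3.25 and 3.92 FPKM, which gives an exact two-sided permutation p of 0.1, the smallest that 3 against 3 allows. The log2 difference of -0.20 (95% interval -0.50 to 0.09) had an adjusted p = 0.447 in limma with Benjamini-Hochberg adjustment, and it was -0.13 (adjusted p = 0.391) without FF replicate 3. The 860 to 1242 reads per library set counting intervals such as 2.62 to 2.98 FPKM in cKO replicate 1 and 3.70 to 4.14 FPKM in FF replicate 3. The value covers the whole gene, exons outside a floxed part included, and every cell type of the heart, so it is only a coarse check of the labels. The paralogues were not past the threshold in limma with Benjamini-Hochberg adjustment: Kdm5a had a log2 difference of 0.44 (SE 0.32, adjusted p = 0.523), of which 0.05 was left without FF replicate 3, and X-linked Kdm5c 0.24 (SE 0.15, adjusted p = 0.455). Y-linked Kdm5d was below the filter, with 0.854 FPKM in FF replicate 3, 2.02 FPKM in cKO replicate 3 and at most 0.0167 FPKM in the other libraries.

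Among the differences between cKO and FF hearts were a gain of the slow myosin Myh7 and a loss of the sugar and lipid metabolism genes Fbp2 and Ech1. Myh7, the myosin heavy chain of the fetal ventricle, rose from 99.3 ± 21.4 to 673 ± 84.2 FPKM (SD, n = 3 each), with an adjusted p = 0.0168 (limma, Benjamini-Hochberg). In all, 21 genes changed of 12678 tested, 9 higher and 12 lower in cKO, and 18 of them code for proteins. Among the higher genes, Klhl38 went from 0.635 ± 0.274 to 5.90 ± 0.967 FPKM and Hif3a, a hypoxia-inducible factor subunit, from 2.46 ± 0.947 to 12.4 ± 1.63. Flcn, the folliculin tumour suppressor, went from 8.16 ± 1.06 to 26.9 ± 1.97. Frmd5, the cell adhesion gene Ncam1, Tmem164 and the receptor gene Gpr157 rose by 1.25, 1.22, 1.16 and 1.04 on the log2 scale.

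Lower genes included Fbp2, the muscle fructose bisphosphatase, from 7.87 ± 2.38 to 0.659 ± 0.384 FPKM, and Ech1, an enzyme of unsaturated fatty acid breakdown, from 199 ± 11.2 to 79.3 ± 8.44. The lipid droplet genes fell too, Cidea from 23.9 ± 0.912 to 9.54 ± 1.16 and Fitm1 from 41.9 ± 5.05 to 19.1 ± 0.396 (SD, n = 3 each). Apln, the peptide ligand of the apelin receptor, went from 20.7 ± 0.637 to 6.44 ± 1.23 FPKM and the endothelial gene Apold1 from 25.4 ± 2.27 to 7.91 ± 0.641. The replication licensing genes Mcm3 and Mcm5 had log2 differences of -1.48 (SE 0.18) and -1.33 (SE 0.15), and the neutrophil granule gene Ngp -1.46 (SE 0.16). Adjusted p-values of these genes lay between 0.0247 and 0.0497 in limma with Benjamini-Hochberg adjustment. Mir6999, a microRNA gene inside Dgkz, also passed, with 11 to 12 reads in FF and 4 to 6 in cKO libraries that may belong to its host. Reads of Myh7 may include those of the antisense transcript Mhrt, and Fitm1 overlaps Gm15932.

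**Figure D2:**
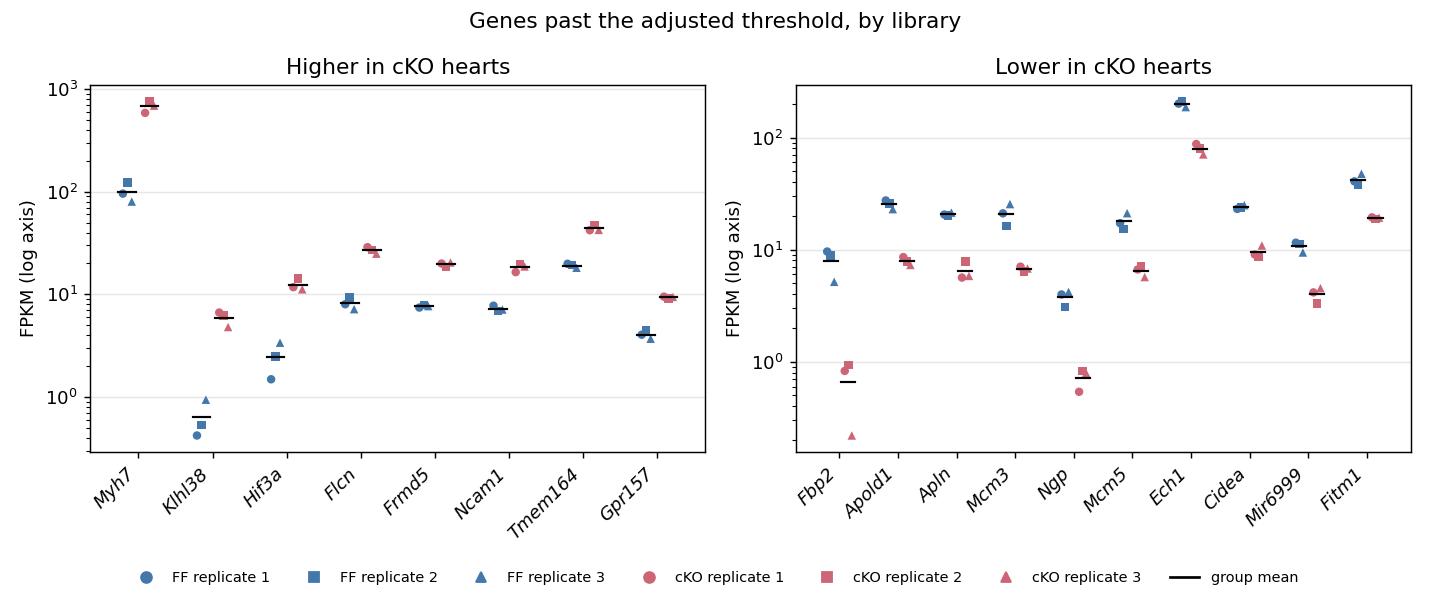
FPKM on a log axis for the genes past the adjusted threshold that the text names, in FF (blue) and cKO (red) libraries, with a point per library and a bar at the group mean. The rule that picked these genes required that values of the 3 cKO hearts not overlap those of the 3 FF hearts. Myh7 reaches the highest level among them.

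Without FF replicate 3, 1520 genes changed, 726 higher and 794 lower, and the 21 genes were among them in the same direction. Leaving out any other library gave 0 genes past the threshold in limma. At an unadjusted p under 0.05 the count was 2041 without FF replicate 1, 1916 without FF replicate 2, and 1449, 1431 and 1268 without cKO replicates 1, 2 and 3, against 2275 with 6 libraries. Many genes named below were picked for the smallest p of their list in these same libraries. That they passed without FF replicate 3 is therefore no separate support. The groups did not overlap at 3547 genes, 28.0% of those tested, where chance gives 10% for a single gene. Genes are not independent of each other, so the excess over that share was not tested. Rescaling outside the mitochondrial genome gave 38 genes higher and 20 lower, and median-ratio scaling 9 higher and 6 lower.

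Cell cycle genes split by phase. The list of S phase genes, which act in DNA replication, was lower in cKO hearts, with a median log2 difference of -0.57 over 38 genes and 36 of them lower (limma camera, adjusted p = 1.2e-13). The list of G2 and mitosis genes was higher, with a median of 0.53 over 53 genes and 48 of them higher (adjusted p = 6.6e-09). The calls were lost when correlation was estimated, with adjusted p = 0.436 with an estimated correlation for S phase and adjusted p = 0.518 with an estimated correlation for G2 and mitosis. Of the S phase genes Mcm5 fell past the threshold over all genes tested, and 20 fell when adjusted over the list alone. For G2 and mitosis these counts were 0 and, adjusted over the list alone, 4 higher. The G2 and mitosis list median of FF replicate 1 lay close to that of cKO replicate 3, at 0.22 and 0.23 above the mean of FF replicates 1 and 2. Kif2c, a kinesin of the mitotic spindle, stood at 3.05 ± 0.370 FPKM in FF and 6.58 ± 0.658 in cKO, Hjurp, the chaperone of the centromeric histone, at 12.7 ± 0.142 and 19.6 ± 0.694, both short of the threshold (SD, n = 3 each). So was Ccnb1, the mitotic cyclin B1, with a log2 difference of 0.84 (SE 0.18). All 3 passed without FF replicate 3 (limma adjusted p = 0.0172, 0.0172 and 0.0445). FF replicate 3, which held thymocyte transcripts, did not carry the S phase difference: without it the median was -0.71 with 25 genes lower, and for G2 and mitosis 0.31 with 10 genes higher, past the threshold over all genes tested.

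Among regulators of the cycle, the list of cell cycle inhibitors was higher, with a median of 0.19 over 18 genes (limma camera, adjusted p = 0.0263; adjusted p = 0.518 with an estimated correlation), 0 members past the threshold over all genes and, adjusted over the list alone, 6 higher and 1 lower. This call was lost without FF replicate 2 (median 0.12, adjusted p = 0.0601), without cKO replicate 2 (median 0.14, adjusted p = 0.0896) and after GC correction (adjusted p = 0.0821), where the median stayed at 0.18. Gadd45b, a stress-induced growth arrest gene, was at 2.93 ± 0.408 FPKM in FF and 7.53 ± 1.31 in cKO, and the pocket protein gene Rbl2 at 4.21 ± 0.287 and 6.92 ± 0.487 (SD, n = 3 each). Ccng2, an atypical cyclin tied to arrest, had a log2 difference of 1.03 (SE 0.13), and Ccnd1, the cyclin of G1, -0.67 (SE 0.12). E2f1, a driver of S phase transcription, stood at -1.05 (SE 0.15) and Mybl2 at -0.92 (SE 0.15). None of these 6 passed the threshold with all libraries, and all 6 did without FF replicate 3, with limma adjusted p from 0.0126 for Ccng2 to 0.0240 for Rbl2. The proliferation gene Mki67 stood at 18.1 ± 12.1 FPKM in FF and 17.2 ± 6.93 in cKO, the mitotic kinase Cdk1 at 14.4 ± 4.62 and 14.4 ± 2.91 and Ccnd2 at 19.2 ± 5.86 and 20.7 ± 1.90. Aurkb was at 8.37 ± 0.622 and 8.72 ± 0.320 FPKM and Cdkn1c at 27.5 ± 10.3 and 30.5 ± 3.23. None of these 5 passed the threshold, with or without FF replicate 3, though without it Mki67 stood at -0.51 and Cdkn1c at 0.48. Cdkn1a had a log2 difference of -0.75 (SE 0.21) and Meis1, a regulator of cardiomyocyte cell cycle exit, 0.42 (SE 0.13), both short of the threshold. Neither the E2F and DREAM list (median -0.12, adjusted p = 0.108) nor the replication-dependent histones (median -0.38, adjusted p = 0.0519, past the threshold in 10 of 20 alternatives) nor the cyclins and cyclin-dependent kinases (median 0.04, adjusted p = 0.821) passed in limma camera.

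Fetal isoforms and stress genes of heart muscle were higher as a list in cKO hearts, while the list median of FF replicate 3 lay at the cKO level. The list of fetal sarcomere and stress genes had a median log2 difference of 0.53 over 15 genes, 14 of them higher (limma camera, adjusted p = 3.4e-05; adjusted p = 0.436 with an estimated correlation). Myh7 rose past the threshold over all genes tested, and 3 members rose when adjusted over the list alone. Nppb, the natriuretic peptide gene induced by wall stress, stood at 128 ± 35.4 FPKM in FF and 444 ± 88.3 in cKO (adjusted p = 0.0577, limma), and Ankrd1, a mechanical stress gene, at 164 ± 33.4 and 406 ± 15.4 (adjusted p = 0.0562, limma). Nppa, high in atria, was at 252 ± 213 and 608 ± 278 FPKM. The alpha myosin Myh6, at 2300 ± 43.6 and 2548 ± 301 FPKM, the fetal troponin Tnni1, at 318 ± 25.4 and 289 ± 12.1, and the adult troponin Tnni3, at 785 ± 73.0 and 607 ± 117, did not pass the threshold (SD, n = 3 each). The adult sarcomere list had a median of 0.15 (limma camera, adjusted p = 0.262), with Myom1 of the M band at a log2 difference of 0.91 (SE 0.16) and Tpm1 at -0.46 (SE 0.12). Calcium handling genes (median 0.14, adjusted p = 0.212), with Slc8a1 at 0.97 (SE 0.26), and cardiac transcription factors (median 0.12, adjusted p = 0.280), with Hey2 at 1.10 (SE 0.21), did not pass in limma camera. The per-library median of the fetal list was 0.59 in FF replicate 3, against 0.57, 0.77 and 0.90 in cKO hearts. The list's difference was 0.76 without FF replicate 3, with 9 members past the threshold over all genes tested, and 0.37 without FF replicate 1. Atrial markers moved with it, from 0.22 to 0.96 without FF replicate 3 and to -0.32 without FF replicate 1. Nppb, Ankrd1, Nppa, Myom1, Slc8a1 and Hey2 passed without FF replicate 3 (limma adjusted p = 0.0175, 0.0152, 0.0473, 0.0152, 0.0283 and 0.0168).

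**Figure D3:**
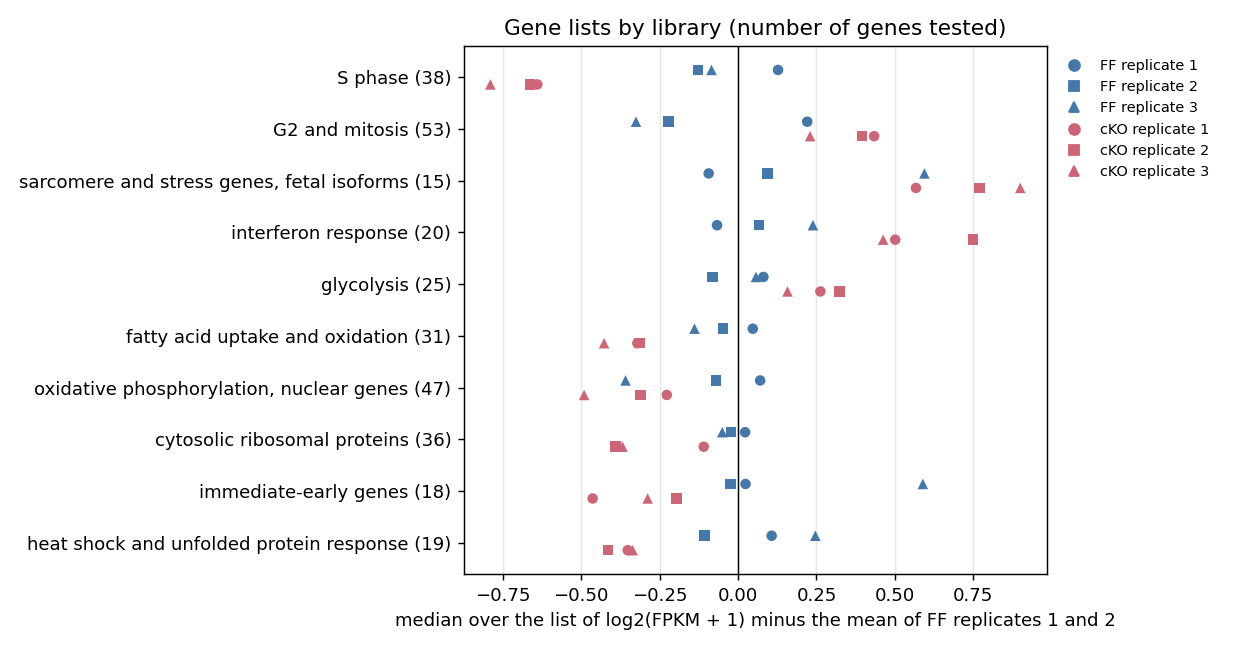
Median over each gene list of log2(FPKM + 1) minus the mean of FF replicates 1 and 2, with a point per library (blue FF, red cKO) and the number of tested genes in brackets. For S phase the 3 cKO hearts lie at -0.64, -0.66 and -0.79, and the FF hearts at 0.13, -0.13 and -0.08. For G2 and mitosis the cKO hearts lie at 0.43, 0.40 and 0.23, and the FF hearts at 0.22, -0.22 and -0.325. FF replicate 3 lies apart from the other FF hearts for immediate-early genes, at 0.59. It lies within the cKO range for fetal sarcomere genes, at 0.59, and oxidative phosphorylation, at -0.36.

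Lists of oxidative metabolism were lower and glycolysis higher in cKO hearts, but FF replicate 3 had list medians within the cKO range for the respiratory chain. They were -0.36 for nuclear oxidative phosphorylation genes, against -0.23, -0.31 and -0.49 in cKO, and -0.68 for the mitochondrial genome, against -0.40, -1.04 and -0.99. Fatty acid uptake and oxidation had a median log2 difference of -0.32 over 31 genes, 22 of them lower (limma camera, adjusted p = 4.6e-04; adjusted p = 0.506 with an estimated correlation). Over all genes tested 1 member fell past the threshold, and when adjusted over the list alone 11 fell and 2 rose. Nuclear genes of oxidative phosphorylation had a median of -0.23, with 37 of 47 lower (limma camera, adjusted p = 0.0026; adjusted p = 0.579 with an estimated correlation), and the mitochondrial genome a median of -0.53, with 14 of 15 lower (adjusted p = 0.0012; adjusted p = 0.551 with an estimated correlation). No member of these 2 lists passed over all genes tested or adjusted over the list alone. Ndufb10 and Ndufb9 of complex I had log2 differences of -0.67 (SE 0.13) and -0.66 (SE 0.16), and mt-Co1 was at 60065 ± 12624 FPKM in FF and 39369 ± 3755 in cKO (SD, n = 3 each). The abundant mitochondrial transcripts did not follow that median in FF replicate 3, where mt-Co1 was at 74517 FPKM, above the other 5 libraries. Mitochondrial genes took 18.97% of the reads in that library, 17.98% and 18.95% in the other FF libraries and 12.83% to 15.71% in cKO libraries. The oxidative phosphorylation call was lost without FF replicate 1 (adjusted p = 0.107) and with quantile normalization (adjusted p = 0.353), and that of the mitochondrial genome with quantile normalization (adjusted p = 0.124). The medians were -0.33 and -0.79 without FF replicate 3, and -0.0930 for oxidative phosphorylation without FF replicate 1. Quantile normalization gave medians of -0.20 for fatty acid genes (adjusted p = 0.0168), -0.13 for each respiratory chain list and 0.38 for glycolysis. Glycolysis had a median of 0.24, with 19 of 25 genes higher (limma camera, adjusted p = 0.0016; adjusted p = 0.526 with an estimated correlation), 0 past the threshold over all genes and 5 higher when adjusted over the list alone. The enolase gene Eno1 stood at 61.2 ± 4.72 FPKM in FF and 94.7 ± 4.01 in cKO, and aldolase C (Aldoc) at 2.26 ± 0.312 and 4.41 ± 0.383. These 2 genes, Ndufb10 and Ndufb9 were short of the threshold and passed without FF replicate 3 (limma adjusted p = 0.0175, 0.0175, 0.0196 and 0.0394).

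Ribosomal protein, immediate-early, protein folding and inflammation lists were lower in cKO hearts, and interferon response genes higher. Cytosolic ribosomal proteins, many with processed pseudogenes that can share reads, had a median log2 difference of -0.30 with 35 of 36 lower (limma camera, adjusted p = 1.2e-06; adjusted p = 0.506 with an estimated correlation). The median was -0.17 with quantile normalization (adjusted p = 0.0039). Rps15 was at 491 ± 53.7 FPKM in FF and 330 ± 47.3 in cKO and Rps14 at 162 ± 16.8 and 101 ± 24.2 (SD, n = 3 each). Immediate-early genes had a median of -0.41 with 16 of 18 lower (adjusted p = 1.9e-04; adjusted p = 0.526 with an estimated correlation). FF replicate 3 lay at 0.59 for them, and without it their median was -0.27 (adjusted p = 0.0136; adjusted p = 0.693 with an estimated correlation). Heat shock and unfolded protein response genes had a median of -0.40 with 12 of 19 lower (adjusted p = 0.0030; adjusted p = 0.506 with an estimated correlation). The 8 inflammation genes tested were all lower, with a median of -0.63 (adjusted p = 0.0030; adjusted p = 0.436 with an estimated correlation). Over the alternatives the inflammation median ran from -0.92 to -0.27, and without FF replicate 3 it was -0.52 with 7 lower and 1 higher. Interferon response genes had a median of 0.58 with 17 of 20 higher (adjusted p = 8.3e-06; adjusted p = 0.506 with an estimated correlation), a call that ended when the filter was a mean FPKM of at least 5 (adjusted p = 0.0509). None of these 5 lists had a member past the threshold over all genes. Adjusted over the list alone, 5 immediate-early genes and 8 stress genes were lower, 1 stress gene and 5 interferon genes were higher, and 0 ribosomal or inflammation genes passed. As values short of the threshold, Klf4 stood at -1.21 (SE 0.16), the phosphatase gene Dusp1 at -1.05 (SE 0.20) and the endoplasmic reticulum genes Manf at -1.22 (SE 0.15) and Creld2 at -0.83 (SE 0.13). S100a9 was at -0.84 (SE 0.24), Socs3 at -0.70 (SE 0.24) and the antiviral genes Rsad2 and Ifi44 at 1.12 (SE 0.20) and 0.78 (SE 0.17). Of these 8, all but Socs3 (-0.46, adjusted p = 0.0741) passed without FF replicate 3, with limma adjusted p from 0.0116 for S100a9 to 0.0307 for Ifi44.

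Among chromatin regulators, histone lysine demethylases outside the KDM5 family were slightly higher, with a median of 0.25 and 13 of 15 higher (limma camera, adjusted p = 0.0234; adjusted p = 0.436 with an estimated correlation). No member passed over all genes and 1 rose when adjusted over the list alone. Kdm3a stood at 6.39 ± 0.931 FPKM in FF and 10.5 ± 0.678 in cKO and Kdm2a at 4.93 ± 0.729 and 6.96 ± 0.635 (SD, n = 3 each). The writers and erasers of H3K4 methylation had a median of 0.14 (limma camera, adjusted p = 0.108), with Setd1b at 0.79 (SE 0.19) and Setd7 at 0.48 (SE 0.20), and did not pass. Leaving out FF replicate 3 gave 0.99 for Setd1b (limma adjusted p = 0.0164) and 0.26 for Setd7 (adjusted p = 0.0960). The imprinted growth network was higher, with a median of 0.45 and 12 of 14 higher (limma camera, adjusted p = 0.0261; adjusted p = 0.436 with an estimated correlation), 0 past the threshold over all genes and, adjusted over the list alone, 3 higher and 1 lower. Its Grb10, an inhibitor of insulin signalling, stood at 72.2 ± 2.94 and 103 ± 3.04 FPKM and Dcn at 71.9 ± 8.62 and 42.4 ± 4.78. Kdm3a, Grb10 and Dcn were short of the threshold with all libraries and passed without FF replicate 3 (limma adjusted p = 0.0240, 0.0217 and 0.0258), and Kdm2a did not. Both list calls ended without FF replicate 1 (median 0.16, adjusted p = 0.0800 for the demethylases and median 0.38, adjusted p = 0.0726 for the imprinted network, limma camera).

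Of the marker lists for cells other than heart muscle, the 3 that passed (thymus, extracellular matrix and macrophage) did not pass without FF replicate 3. Thymus and lymphocyte markers had a median of -1.16 with 13 of 13 lower in cKO (limma camera, adjusted p = 0.0234; adjusted p = 0.593 with an estimated correlation), and without that library 0.02 (adjusted p = 0.909). It was -1.74 without FF replicate 1 and -1.77 without FF replicate 2. Trbc2 averaged 36.7 ± 62.6 FPKM in FF and 0.0975 ± 0.0845 in cKO, and Thy1 16.7 ± 19.3 and 4.63 ± 0.931 (SD, n = 3 each). Extracellular matrix genes had a median of -0.27 with 29 of 31 lower (adjusted p = 0.0025; adjusted p = 0.579 with an estimated correlation), a call that ended without FF replicate 3 (median -0.02, adjusted p = 0.474) and without cKO replicate 1 (median -0.12, adjusted p = 0.0645). Without FF replicate 1 the matrix median was -0.52. Macrophage markers had a median of -0.62 with 10 of 13 lower (adjusted p = 0.0462; adjusted p = 0.579 with an estimated correlation), and not past the threshold without FF replicate 3 (median -0.26, adjusted p = 0.280) or without cKO replicate 1 (median -0.47, adjusted p = 0.0831). In these 3 lists 0 members passed over all genes. Adjusted over the list alone, 1 matrix gene and 3 macrophage genes were lower and 1 macrophage gene was higher. Lyve1, of resident macrophages and lymphatic vessels, had a log2 difference of 0.80 (SE 0.12). Adgre1 stood at 2.39 ± 0.643 FPKM in FF and 1.15 ± 0.222 in cKO and Timp1 at 11.1 ± 1.84 and 7.49 ± 0.614. Epicardial (median -0.38, adjusted p = 0.0519, past the threshold in 11 of 21 alternatives and opposite in direction in 3), endothelial (median -0.17, adjusted p = 0.0704) and fibroblast markers (median -0.18, adjusted p = 0.127) did not pass in limma camera. Their members stood at log2 differences short of the threshold, Aldh1a2 at -1.14 (SE 0.17), Wt1 at -0.61 (SE 0.13) and Cldn5 at -1.06 (SE 0.17). These 3 and Lyve1 passed without FF replicate 3 (limma adjusted p = 0.0175, 0.0368, 0.0207 and 0.0164), and Adgre1 and Timp1 did not. Other members went the other way. In that fit 2 epicardial genes passed over all genes as higher and 2 as lower, with a list median of 0.04. Of the endothelial genes 2 passed as higher and 3 as lower. In all, 18 of 42 lists passed, 7 higher and 11 lower, and 15 passed in the same direction without FF replicate 3; with an estimated correlation 0 passed.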

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

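The comparison rests on few libraries, and the count of changed genes moved with most settings. Against 21 genes it was 11 with a pseudocount of 0.1, 0 with no filter (3210 at an unadjusted p under 0.05, limma), 53 at a mean FPKM of at least 5, 59 with quantile normalization, 58 after rescaling, 13 with robust priors, 4300 with library weights, 65 over protein-coding genes and 2275 without adjustment. Among the settings chosen after seeing the data it was 487 with the GC correction, 2034 with that and without the third FF library, 11 with voom, 2824 with voom and quality weights and 118 with a term for Y-linked reads. Leaving out a library in turn gave 0 to 1520 genes, and the cause was not tested beyond the spread of FF replicate 3. The 18 named genes past the threshold kept their direction in every setting that tested them, with 216 of their values under alternatives past it and 159 short of it. Whether the numbers of the samples pair them stays open. Same-numbered deviations from the group means correlated at 0.38, -0.24 and 0.24, and the replicate block left 2 genes. FF replicate 3 weighs on the FF deviations, so these correlations cannot exclude a pairing. Of the lists, 14 to 25 passed over settings with the preset correlation against 18. With an estimated correlation 0 passed (4 at an unadjusted p under 0.05, limma camera), and 0 with that and without the third FF library (2 unadjusted), while 5 passed in the directional test of limma fry. Adjusted p ranged from 1.7e-04 to 0.962 over the settings for the thymus list, 1.8e-06 to 0.584 for extracellular matrix, 0.0029 to 0.316 for macrophages, 1.0e-06 to 0.353 for oxidative phosphorylation, 5.8e-07 to 0.124 for the mitochondrial genome, 1.1e-06 to 0.0509 for interferon, 0.0116 to 0.0896 for cell cycle inhibitors, 0.0041 to 0.0800 for demethylases and 0.0012 to 0.0726 for the imprinted network (limma camera). Kdm5b stayed lower and short of the threshold (log2 -0.27 to -0.12, limma adjusted p 0.163 to 0.747), and had no value at a mean FPKM of at least 5. Some directions turned. With library weights Ccnd2 was at -0.0293, Mki67 at -0.35 and the epicardial list at 0.11. With the GC correction and without the third FF library Ccnd2 was at -0.15, Cdk1 at -0.16, Mki67 at -0.50, the cyclin list at -0.0817, the thymus list at -0.0052 and the epicardial list at -0.0056. With the GC correction alone the cyclin list was at -0.0326 and the ventricular list at -0.0663. For the thymus, epicardial and ventricular lists under these GC settings it was the direction of the camera test that turned, not the sign of the median. With voom and quality weights Ccnd2 was at -0.0756, Cdk1 at -0.13, Mki67 at -0.57 and the cyclin list at -0.10. Xist was at 0.66 with voom, and the ventricular list at 0.0817 with quantile normalization. Leaving out a library in turn, medians ranged from -1.77 to 0.0161 for the thymus list, -0.64 to 0.0417 for the epicardial, -0.32 to 0.96 for the atrial, -0.21 to 0.0064 for the ventricular and -0.13 to 0.25 for the cyclin list. Log2 differences ranged from -0.12 to 0.31 for Ccnd2, -0.13 to 0.25 for Cdk1, -0.51 to 0.60 for Mki67, -2.24 to 1.48 for Xist and -0.32 to 1.28 for Ddx3y.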

Other observations

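Chamber and sex markers varied between hearts of the same group, and the lists on regulators were written after the data were seen. Myl7 and Sln, the myosin light chain and the calcium pump inhibitor of the atria, were chosen after their values were seen. Myl7 stood at 45.3, 357 and 1019 FPKM in the FF and 337, 199 and 599 FPKM in the cKO libraries, and Sln at 2.53, 19.4 and 109 against 20.7, 12.3 and 40.8. Atrial markers had a median log2 difference of 0.22 (limma camera, adjusted p = 0.184), 0.96 without FF replicate 3 (adjusted p = 6.7e-04; adjusted p = 0.693 with an estimated correlation) and -0.32 without FF replicate 1. The ventricular list stood at -0.16 (adjusted p = 0.732). Xist, expressed from the inactive X chromosome, was at 0.0087 FPKM in FF replicate 3 and 0.0744 in cKO replicate 3, against 27.1 to 63.0 in the other libraries. Y-linked Ddx3y was at 0.985 and 8.21 FPKM in the same libraries and at most 0.0097 elsewhere.

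Growth signalling and regulator targets gave further values. The IGF and insulin list had a median of 0.06 (limma camera, adjusted p = 0.0865) and 0.35 without FF replicate 3 (adjusted p = 0.0112; adjusted p = 0.693 with an estimated correlation), but -0.0524 without FF replicate 1 and -0.17 without FF replicate 2. Its member Pik3ip1, an inhibitor of PI3 kinase, stood at 5.18 ± 1.17 FPKM in FF and 19.6 ± 5.04 in cKO (SD, n = 3 each). Igf2r, the receptor that clears IGF2 and overlaps Airn, stood at 60.4 ± 1.83 and 112.7 ± 9.23 FPKM, and both genes were short of the threshold and passed without FF replicate 3 (limma adjusted p = 0.0126 and 0.0159). Erythroid markers had a median of 0.09 (adjusted p = 0.0572) and 0.36 without FF replicate 3 (adjusted p = 0.0229; adjusted p = 0.693 with an estimated correlation). Among lists written after the data were seen, targets of the lipid regulator PPARA had a median of -0.36 with 26 of 33 lower (limma camera, adjusted p = 5.3e-08; adjusted p = 0.0683 with an estimated correlation). Targets of FOXO factors stood at 0.33 with 16 of 24 higher (adjusted p = 4.7e-05; adjusted p = 0.184 with an estimated correlation) and glucocorticoid receptor targets at 0.16 (adjusted p = 0.333; adjusted p = 0.748 with an estimated correlation). Adjustment for these regulator lists ran over them alone, so their adjusted p-values cannot be set beside those of the other lists. The regulator lists were written after these same libraries were seen, so their p-values are no separate support for a role of these regulators. Of 67 tested genes within 5 megabases of Kdm5b, 0 passed the threshold in limma (9 at an unadjusted p under 0.05), and 4 did without FF replicate 3, against 8.03 expected (Fisher's exact two-sided p = 0.183).

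FF replicate 3 stood apart from the other 5 libraries, and the tests of thymus tissue and of the genes that differ most, and these marker genes, were chosen after the result was seen. Thymus markers lay 3.57 log2 units above the mean of the other FF hearts in the median, with 13 of 13 highest there (Trbc1 59.5 FPKM, Tcf7 55.6, Lck 31.3, Cd8b1 22.3; Thy1, at 3.97 to 5.70 FPKM elsewhere, at 38.9), so thymus carried along with the heart may be a part of it. A GC bias as the whole cause is argued against, since after GC correction its highest correlation was 0.932, below the lowest of 0.959 among the others. A wrong group label as the whole cause is argued against, by a comparison not set beforehand. Its correlations with the cKO libraries were 0.880, 0.909 and 0.907, below the lowest of 0.978 among those. With FF replicates 1 and 2 they were 0.890 and 0.900, so these correlations place it with neither group. Whether its label is wrong as well stays open: of the 1520 genes called from the other 5 libraries it lay nearer the FF mean at 54.9%, short of the 60% set beforehand. The share was 62.8% after GC correction and 69.0% at the 158 genes differing by over 1 log2 unit, both looked at after that test had missed its bound.

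The fall of S phase genes beside higher G2 and mitosis genes was weighed with tests that were all chosen after the result was seen. Thymus cells in FF replicate 3 are argued against for the S phase genes, whose median was -0.71 without that library. GC content is argued against for both, with medians of -0.59 for S phase and 0.41 for G2 and mitosis after correction. Over the settings the adjusted p of limma camera ran from 3.1e-19 to 1.9e-07 for S phase and from 3.7e-14 to 4.1e-05 for G2 and mitosis, but with an estimated correlation neither passed. An untested hypothesis is that loss of Kdm5b may change how heart muscle cells pass the cycle, and a shift in the share of cycling cell types stays open beside it; DNA synthesis and mitosis counted by cell type in both genotypes would decide.

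Kdm5b was only slightly lower in cKO hearts, and both tests of this were chosen after the result was seen. Labels swapped for some of the other 5 libraries are argued against, since the lowest correlation within a group, 0.978, exceeded the highest between groups, 0.966. An exchange of the group names as a whole would leave these correlations unchanged, so they cannot test it. Reads from exons outside the deleted part, or from cells without the deletion, may keep the gene-level value at 17.3% lower, and gene-level values leave this open. Of the 10 splits of the 6 libraries into 3 and 3, only the real 1 gave 21 genes and the highest other gave 0 (1661 against 2275 at an unadjusted p under 0.05, limma). The count of 1661 came from the split that put FF replicate 3 with cKO replicates 2 and 3. A share under 0.05 is out of reach with 10 splits.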
